A study of Homo sapiens with 6 samples.

How the data were processed

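Ribosome profiling was used on 6 libraries of HEK293T-REx cells, a tetracycline-repressor derivative of the human embryonic kidney line. Ribosome profiling sequences the short RNA pieces that ribosomes shield from nuclease, so a count of such footprints on a coding region follows how many ribosomes were translating it. Per the labels' protocols, footprints were made with RNase I, ribosomes were pelleted, RNA was extracted, a linker was ligated, rRNA was depleted, and cDNA was circularized and amplified. The naive line and the aglaiacized line each had 2 libraries from cells given the solvent DMSO and 1 library from cells given RocA. No dose or time was used here. Nothing in the labels says that the DMSO replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

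The authors deposited raw counts, 1 value per transcript row, with no header and no normalization. The build hg19 and the tools CASAVA 1.8, Bowtie2 2.1.0 and TopHat2 2.0.9 are listed in the submitters' processing notes. The program that counted the footprints, its treatment of reads with several matches and the removal of rRNA reads are not given in the sources used here. Each deposited file has another column, a whole-number length of 15 to 35982 per transcript, whose unit is not stated. Its values have the size of protein lengths, and it is taken here as a coding length in length units, a reading that was not tested. Of 82960 rows, 19269 had no such length, and these held 0 counts in all 6 libraries, so they stayed out.

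Many rows repeat the counts of another row in all 6 libraries, as isoforms of 1 gene do when a read is counted in more than 1 of them; the counting rule itself is not stated. The 50582 rows with a length and a count were reduced to 38543 sets with distinct counts over the 6 libraries, called transcript models. The first row's identifier and the longest length of each set were kept. Models of 1 gene that share part of their reads remained separate, so numbers of models are not numbers of genes. This choice was made after the data were examined, since the planned choice of 1 transcript per gene could not be run. In all, 3 sets had been fitted and their calls seen before the present one was taken as the main set: models with a mean count of at least 20, models with a mean count of at least 100, and models without rows nested in a larger neighbour. The calls of the other sets ran from 2691 to 15350 per comparison. Total counts over all rows ran from 9546180 to 33640289 per library.

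The files do not pair the transcript identifiers with gene names. Of the 82960 identifiers, 1 was found among the synonyms of the reference gene table (GRCh38.p14), and it had no listed length. Genes are therefore not named. The plan, fixed before the data were examined, held 19 gene lists, a calibration on mitochondrially encoded genes, a 5′ UTR purine measure, 1 transcript per gene and a check of the eIF4A genes, which would have tested the labels of the lines. These need gene names or sequences and were not run, and neither was the alternative without ribosomal protein genes. The rule for named genes took the models with the largest rise and fall past the threshold, with a mean count of at least 50 and no overlap between the libraries compared. Of these, the identifiers of the first 2 that rose and the first 2 that fell in naive cells are printed.

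Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors) on the 31237 models with a mean count of at least 20. One model of 4 groups was fitted to all 6 libraries, which left 2 residual degrees of freedom. Each RocA group had 1 library. Its own spread was not measured, and it was assumed to vary like the DMSO libraries. The 2 DMSO pairs did not vary alike. Against counting noise, the chi-square per degree of freedom was 1.873 for the naive and 4.474 for the aglaiacized pair, whose libraries were also deeper. The spread of a model was fitted over both lines together, so numbers of calls in the 2 lines do not rest on each line's own spread. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, all tests were two-sided, and the standard error (SE) was the size of the log2 fold change divided by the root of the F statistic. The contrasts were RocA against DMSO in each line, the difference between these responses, and aglaiacized against naive cells in DMSO. CPM values were computed here from the TMM-scaled library sizes.

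Spread and correlation were computed on log2(CPM + 1) for the 20211 models with a mean count of at least 100, with no p-value because models are not replicates. Length groups were chosen after the data were examined. They are 5 groups of about equal size of the tested models, and medians against single libraries used log2(CPM + 0.01). Confidence intervals of shares are 95% Wilson intervals and cover counting error only, as does the limit of 3 counts used for a count of 0. The intervals treat counts as independent. Where models share reads, 1 read may be counted more than once, and the intervals are then too narrow.

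The edgeR step was tested on simulated data with the real library sizes and the mean abundances of the 31237 models over all 6 libraries. Dispersions came from the fitted trend with abundance, not from each model. For each simulated effect (RocA in naive cells, RocA in aglaiacized cells, the line), 200 models were changed by 1.5, 2 or 4-fold in about equal numbers. For RocA in naive cells it recovered 20.9% of 1.5-fold, 58.2% of 2-fold and 87.9% of 4-fold changes, with 4 false calls. For RocA in aglaiacized cells it recovered 14.9%, 59.7% and 89.4%, with 5 false calls. For the difference of responses it recovered 5.97%, 36.6% and 75.8%, with 4 false calls. For the lines in DMSO it recovered 59.7%, 92.5% and 100%, with 7 false calls. Far fewer models were changed than were called in the data, so these recovery rates hold for the simulated setting only. Simulated RocA libraries had the dispersions of the other libraries, and models were drawn independently. The false calls thus do not test the unmeasured spread of RocA or reads shared between models. They also do not test spread that differs between models of similar abundance. The step was first required to recover over 80% of 4-fold changes in each comparison. The difference of responses did not reach this, and the requirement was lowered to 70% without a change to the step. The step that leaves out nested rows kept 185 of 200 unrelated simulated rows and 0 of 200 nested ones, and its requirement was lowered from over 190 to over 170 rows. Its unrelated rows were simulated to vary independently between libraries. This does not show that unrelated rows with few counts or little change are kept. Alternatives were RLE factors, DESeq2 1.42.0, other count filters, fits on the compared groups alone, thinning to the smallest library, a replicate block and leaving out each DMSO library. Total counts without scaling, every row with a length and a count, and a set without rows nested in a larger neighbour were added after the data were examined.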

Results

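Footprints were counted in 2 HEK293T-REx lines, naive and aglaiacized, with DMSO (n = 2 libraries per line) or RocA (n = 1 library per line). RocA, or rocaglamide A, is a natural product of Aglaia plants that clamps the translation initiation helicase eIF4A onto polypurine RNA. In the study the aglaiacized line carries an eIF4A1 with residues of Aglaia, a plant that resists its own compound, although the labels do not explain the word and the line was not checked against its eIF4A counts here. The question of the series is how these residues bear on sensitivity to RocA. The libraries held 18459239 and 18731972 counts over distinct transcript models in naive DMSO and 8219273 in naive RocA. They held 21337146 and 28428267 in aglaiacized DMSO and 8316797 in aglaiacized RocA. RocA libraries thus had 0.442 times the mean DMSO total in naive cells and 0.334 times in aglaiacized cells. These totals reflect sequencing as well as translation, so every change below is relative to the other transcripts of the same library. No mRNA amounts were used here, so a change in footprints may reflect the amount of an mRNA as well as its translation.

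Fewer transcripts held the bulk of the footprints in the RocA libraries than in the DMSO libraries of the same line. The 100 most abundant models took 13.9% and 13.7% of counts in naive DMSO and 22.3% (95% Wilson interval 22.23% to 22.29%) in naive RocA. They took 15.02% and 15.41% in aglaiacized DMSO and 19.6% (19.61% to 19.67%) in aglaiacized RocA. A share of 0.5 of the counts was reached with 1524 and 1538 models in naive DMSO and with 693 in naive RocA. The same point needed 1409 and 1389 models in aglaiacized DMSO and 891 in aglaiacized RocA. An exact permutation test of 2 libraries against 1 cannot go below p = 0.333, and no p-value is given for these shares.

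In naive cells, RocA changed the relative footprint count of 20698 of 31237 transcript models (66.3%). Of these, 10109 rose, with a median log2 fold change of 1.14, and 10589 fell, with a median of -1.40. Rises of at least 2-fold were called for 6061 models and falls of at least 2-fold for 7505. At 4-fold, 927 models rose and 2751 fell. The central 90% of all models lay between -2.45 and 1.8 on the log2 scale. The largest rise among named models was that of uc002hvi.3, from 1.89 ± 0.80 CPM (SD, n = 2) to 36.4 CPM, a log2 fold change of 4.27 (SE 0.23, edgeR adjusted p = 1.5e-32). The model uc003ema.4 went from 9.36 ± 1.78 CPM (SD, n = 2) to 138 CPM, a log2 fold change of 3.88 (SE 0.14, edgeR adjusted p = 4.5e-46). At the other end, uc021ynx.1 fell from 5.47 ± 0.79 CPM (SD, n = 2) to 0 counts, which is at least 11.3-fold lower (edgeR adjusted p = 1.26e-10). The model uc010sta.1 fell from 5.20 ± 0.68 CPM (SD, n = 2) to 0 counts, at least 10.7-fold lower (edgeR adjusted p = 2.21e-10). Both bounds set the single RocA library at 3 counts, or 0.485 CPM. In all, 85 tested models had 0 counts in naive RocA and 14 had 0 in aglaiacized RocA. The balance of rises and falls depended on scaling: with total counts and no scaling factor, 5749 models rose and 16632 fell, and the median of all models moved from -0.10 to -0.68. With RLE factors 10791 rose and 9708 fell. DESeq2, which changes the test as well as the factors, called 8506 rises and 6878 falls. The calls rest on the spread of the DMSO pairs, since RocA had no replicate.

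In aglaiacized cells, RocA changed 15272 of the 31237 models (48.9%). Of these, 7668 rose, with a median log2 fold change of 0.76, and 7604 fell, with a median of -1.04. Rises of at least 2-fold were called for 1576 models and falls of at least 2-fold for 4052. At 4-fold, 15 models rose and 757 fell. The 15 rises include 5 models with similar counts, only 6 to 8 in aglaiacized RocA, which may share reads. The central 90% of all models lay between -1.62 and 1.01. The model uc002hvi.3 rose here too, from 1.68 ± 0.90 CPM (SD, n = 2) to 12.9 CPM (log2 fold change 2.88, SE 0.27, edgeR adjusted p = 3.34e-16). Without aglaiacized DMSO replicate 2, the log2 fold change of uc002hvi.3 was 3.63 (edgeR adjusted p = 2.79e-32). The model uc003ema.4 rose from 12.6 ± 0.73 CPM (SD, n = 2) to 24.4 CPM (log2 fold change 0.95, SE 0.17, edgeR adjusted p = 1.05e-06). The model uc021ynx.1, at 0 counts in naive RocA, had 10 counts in aglaiacized RocA and fell by 1.41 on the log2 scale (SE 0.43, edgeR adjusted p = 0.00413). The model uc010sta.1 had 9 counts there and fell by 1.99 (SE 0.42, edgeR adjusted p = 3.49e-05). With total counts and no scaling factor, 4310 models rose and 11876 fell, and the median of all models was -0.34 instead of -0.04. DESeq2 called 9270 models, 5393 up and 3877 down, and did not call the fall of uc021ynx.1, although its log2 fold change of -1.37 was close to that of edgeR (DESeq2 adjusted p = 0.104).

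The response to RocA was wider in naive than in aglaiacized cells. Over 20211 well-covered models, the SD of the log2 fold changes, RocA over a single DMSO library, was 1.15 against either naive DMSO library. Against the aglaiacized DMSO libraries it was 0.702 and 0.695. One DMSO replicate over the other gave 0.140 in naive and 0.179 in aglaiacized cells. The ratio of the mean SDs, naive over aglaiacized, was 1.64. With 1 RocA library per line, this ratio has no replicate check.

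**Figure D1:**
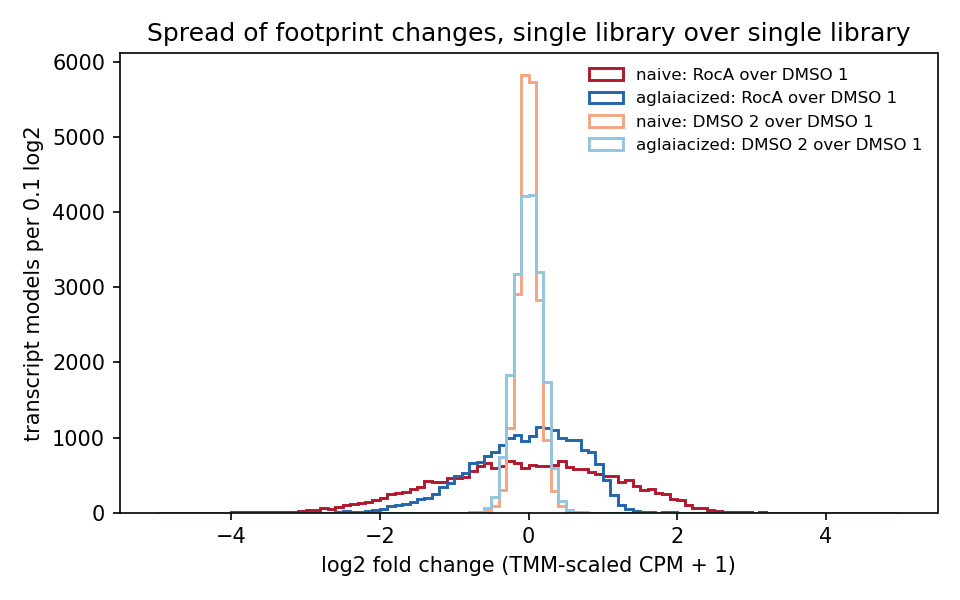
Histograms of log2 fold changes of TMM-scaled CPM + 1 (x axis) over 20211 transcript models with a mean count of at least 100 (y axis, models per bin), for RocA over DMSO replicate 1 and for DMSO replicate 2 over 1 in each line. The naive RocA distribution (SD 1.15) is wider than the aglaiacized one (SD 0.702), and both are wider than the DMSO pairs (SD 0.140 and 0.179).

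The transcripts that rose or fell in one line moved the same way in the other more often than independent lists would. Of the 10109 models that rose in naive cells, 6536 (64.7%) rose in aglaiacized cells and 98 fell, where independent lists would share 2482 rises. Of the 10589 that fell in naive cells, 6281 (59.3%) fell in aglaiacized cells and 116 rose, where independent lists would share 2578 falls. Across models, the 2 responses, which share no library, correlated with Spearman rho 0.871 and Pearson r 0.865, and 85.0% had the same sign. Using single DMSO libraries, rho ran from 0.840 to 0.883. These are correlations across transcript models, which are not independent replicates.

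The difference between the responses of the 2 lines was itself past the threshold for 7992 of 31237 models (25.6%). Among the 6061 models with a called rise of at least 2-fold in naive cells, the median log2 fold change was 1.46 in naive and 0.77 in aglaiacized cells. Among the 7505 models with a called fall of at least 2-fold in naive cells, the medians were -1.74 and -0.93. Choosing models by their naive response inflates that response, so the choice was also made the other way. The 1576 called rises of at least 2-fold in aglaiacized cells had medians of 1.72 in naive and 1.12 in aglaiacized cells, and the 4052 falls had medians of -1.86 and -1.45. Among these rises the difference was called in 721 models toward a larger rise in naive cells and in 42 toward a smaller one. Among these falls it was called in 633 toward a larger fall in naive cells and in 145 toward a smaller one. Both lines' calls went opposite ways in 214 models. The difference was called in all 214 of these, which 2 opposite calls from the same fit make nearly certain. DESeq2 called 3941 models for the difference, of 20336 that it gave an adjusted p-value. With total counts and no scaling factor, the split changed from 3533 above and 4459 below 0 to 6629 above and 2472 below.

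**Figure D2:**
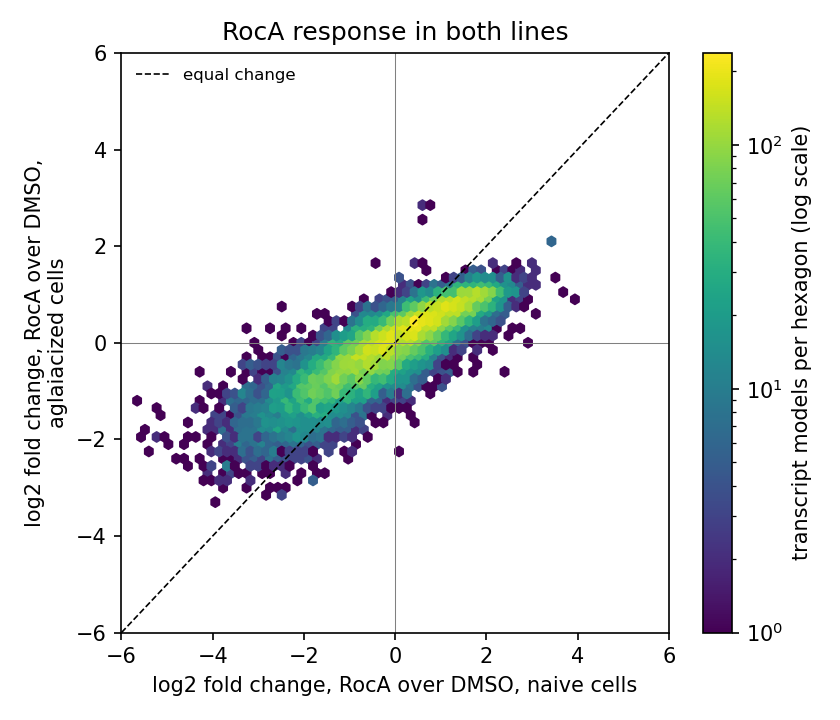
Each hexagon is coloured on a log scale by its number of transcript models (20211 in all), placed by the edgeR log2 fold change of RocA over DMSO in naive cells (x axis) and in aglaiacized cells (y axis). Values beyond the axis range are drawn at its edge. The cloud runs along both directions and is flatter than the dashed line of equal change. Spearman rho was 0.871 for the same models, computed on log2(CPM + 1) and not on the plotted values.

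Transcripts with a short listed length, which is taken as coding length although its unit is not stated, rose relative to those with a long one, and more so in naive cells. The shortest of 5 length groups (6264 models, 16 to 217 length units) had a median log2 fold change of 0.32 under RocA in naive cells. In it, 2754 models rose and 1474 fell. The longest group (6243 models, 773 to 14498 length units) had a median of -0.40, with 1551 models that rose and 2741 that fell. The difference between the 2 groups was 0.72, and it was 0.73 and 0.69 against the single DMSO libraries. In aglaiacized cells the shortest group had a median of 0.10 and the longest a median of -0.11. The difference was 0.22, or 0.25 and 0.21 against single libraries. Between DMSO replicates it was -0.02 in naive and -0.05 in aglaiacized cells, and between the lines in DMSO, aglaiacized over naive, it was 0.11. A scaling factor cancels in such a difference but not in the medians themselves. Across all tested models, the Spearman correlation of the change with listed length was -0.173 for RocA in naive cells and -0.0828 in aglaiacized cells. DMSO replicate 1 over 2 gave 0.0265 in naive and 0.0781 in aglaiacized cells, and the lines in DMSO gave -0.109. By this measure the aglaiacized trend was close in size to that of its DMSO pair and no larger than that between the lines.

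**Figure D3:**
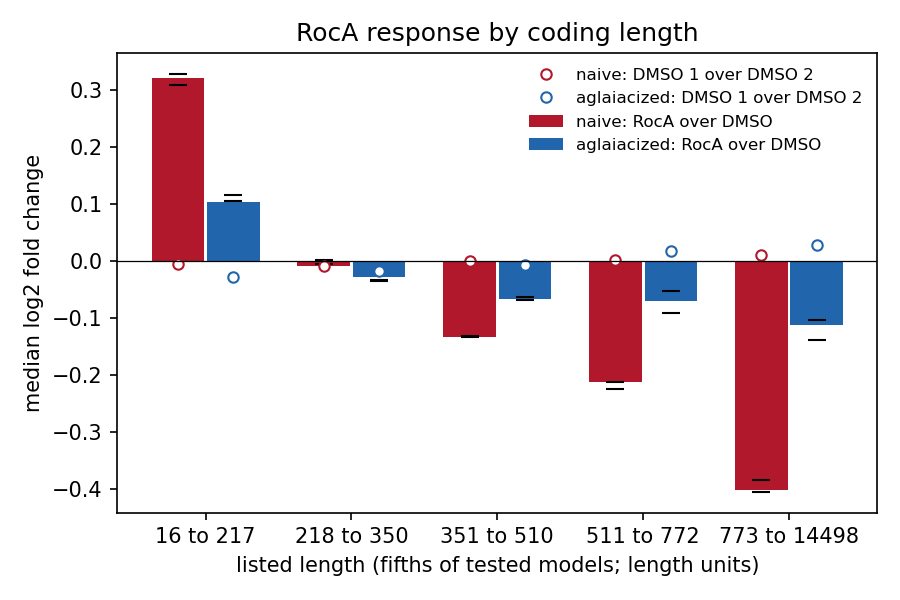
Bars give the median log2 fold change of RocA over DMSO (y axis) in 5 groups of the tested transcript models by listed length (x axis, length units), for naive and aglaiacized cells. Black dashes are the values against each single DMSO library, and open circles are DMSO replicate 1 over 2; the naive bars go from 0.32 in the shortest to -0.40 in the longest group.

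In DMSO alone, 11121 of 31237 models (35.6%) differed between the lines, mostly by small amounts. Of these, 5936 were higher in aglaiacized cells, with a median log2 fold change of 0.49, and 5185 were lower, with a median of -0.51. A difference of at least 2-fold was called for 207 models that were higher and 537 that were lower. At 4-fold, 4 models were higher and 85 lower. Among called models with a mean count of at least 50 and no overlap between the lines, the 5 deepest fitted losses held 234 to 418 counts in each naive DMSO library. They held 1 count in aglaiacized DMSO replicate 1 and 6 or 7 in replicate 2. Such similar counts may mean that these models share reads, so they may not be 5 separate losses. The same 5 models had called rises in aglaiacized RocA, by 2.60 to 2.83 on the log2 scale, with 6 to 8 counts there. The SD of single-library comparisons between the lines, 0.332 and 0.402, was above that of the DMSO pairs. With total counts and no scaling factor, 4670 models were higher and 6776 lower. When a DMSO library of a line was left out, only the DMSO pair of the other line gave the spread. The number of calls was sensitive to the data used, which here includes the pair that gave the spread. It was 5456 without naive DMSO replicate 1 and 5235 without naive DMSO replicate 2. It was 14081 without aglaiacized DMSO replicate 1 and 8815 without aglaiacized DMSO replicate 2. Libraries thinned to 1 depth gave 7212, and DESeq2 gave 3586 of the 20336 models with an adjusted p-value.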

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

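The tests on selection of models, on variation between RocA libraries and on listed length were chosen after the result was seen. The second pattern below, on listed length in naive cells, was added after the data were examined. The printed models and the first pattern stand out because the difference between the responses of the 2 lines passed its own edgeR test in 7992 models. That test takes its spread from the DMSO pairs and holds no spread between RocA libraries, of which each line has 1. For the printed models, the log2 difference of responses, aglaiacized minus naive, was -1.39 for uc002hvi.3 (edgeR adjusted p = 0.00156) and -2.94 for uc003ema.4 (edgeR adjusted p = 3.66e-20). The fitted differences of 8.23 for uc021ynx.1 (edgeR adjusted p = 0.00131) and 7.58 for uc010sta.1 (edgeR adjusted p = 0.00728) rest on 0 counts in naive RocA. They depend on the prior count and are no bound on the effect. The difference of uc002hvi.3 was not called with libraries thinned to 1 depth (-0.85, edgeR adjusted p = 0.185), without aglaiacized DMSO replicate 2 (-0.64, edgeR adjusted p = 0.247) or with DESeq2, where the difference was as large as with edgeR (-1.38, DESeq2 adjusted p = 0.447).

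The first pattern is the smaller response in aglaiacized cells. Choosing models for a large naive response would by itself make the other line look weaker. Yet among models chosen for a called change of at least 2-fold in aglaiacized cells, 68.5% had the larger change in naive cells, which argues against that selection as the whole cause. Depth is argued against as well, since with all libraries thinned to 1 total the ratio of the SDs, naive over aglaiacized, was 1.693. That value covers about 12850 models that kept a mean count of at least 100 after thinning. The set of models thus changed along with the depth. What stays open is variation between RocA libraries, because each line has 1 RocA library, and a difference in the line itself, which the design names but cannot be told apart from a difference between those 2 libraries. Whether mRNA amounts or translation changed is open too, since no mRNA amounts were used.

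The second pattern is the higher response of transcripts with a short than with a long listed length in naive cells, a difference of 0.722 on the log2 scale. A low abundance of one length class does not account for it, since within 5 groups of abundance the smallest difference was 0.425, against at most 0.081 in size between DMSO replicates. Isoform rows that share reads are argued against by the difference of 1.021 without rows nested in a larger neighbour, although that set favours rows with distinct counts. What stays open is variation between RocA libraries, since the only measured spread is that of the DMSO pairs. A change in mRNA amounts stays open as well, since none were used here. A dependence of initiation on features of the longer mRNAs may contribute, and it was not tested because no sequences were used here.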

How the results depend on the processing

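The alternatives in total counts, every row with a length and a count, nested rows and length were chosen after seeing the data, and the others before. Over all alternatives the number of calls ran from 5172 to 23792 for RocA in naive cells, from 4177 to 17567 for RocA in aglaiacized cells, from 2691 to 10267 for the difference and from 3123 to 14081 for the lines in DMSO. The lowest values came from leaving out rows nested in a larger neighbour, which left 6575 of 31237 models to test; the shares called were then 78.7%, 63.5%, 40.9% and 47.5%. In simulated rows that step kept 185 of 200 unrelated neighbours. DESeq2 called 9270 models for RocA in aglaiacized cells, 3941 for the difference and 3586 for the lines in DMSO, with 1817, 10901 and 10901 adjusted p-values not given; the cause was not tested. Thinning to the smallest library gave 7212 calls for the lines in DMSO, where fewer counts remained. Leaving out each DMSO library gave 5235 to 14081 calls for the lines in DMSO, with 5456 and 5235 without naive replicate 1 and 2. The replicate block gave 10580 calls there, 10489 of them shared with the fit without it. Same-numbered DMSO libraries did not deviate together (r = -0.05 across models). This does not show whether they shared a culture or a day, and the RocA libraries carry no number to pair. Unscaled total counts shared 16474 of the 20698 naive calls, direction ignored, but left 25.7% of calls as rises, not 48.8%. In aglaiacized cells it left 26.6% in place of 50.2%, for the difference 72.8% above 0 in place of 44.2%, and for the lines in DMSO 40.8% in place of 53.4%. The alternative without ribosomal protein genes was not run.

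The SD of log2 fold changes in naive and aglaiacized cells was 1.059 and 0.6595 at a mean count of at least 20, 1.195 and 0.6755 at 500, and 1.213 and 0.7409 from the interquartile range. It was 1.174 and 0.6935 after thinning, over about 12850 models that kept a mean count of at least 100. It was 1.232 and 0.7475 with a pseudocount of 0.25, 0.9099 and 0.5518 with a pseudocount of 5, and 1.256 and 0.7573 without nested rows. The ratio of the lines was 1.605 at 20 counts, 1.77 at 500, 1.693 after thinning and 1.659 without nested rows, and naive cells had the wider spread under each of the alternatives run. The Spearman correlation of the 2 responses across models was 0.8211 at 20 counts, 0.9112 at 500, and 0.8416 to 0.8842 with each DMSO library left out. The difference between the shortest and longest length group in naive cells was 0.7821 at 100 counts, 1.021 without nested rows, and 0.6934 to 0.7333 with a DMSO library left out. In aglaiacized cells it was 0.3061 without nested rows and 0.2088 to 0.2534 with a DMSO library left out. Of the recomputed changes of the 4 printed models, 146 kept their side of the threshold, 4 lost their call and 0 changed sign. DESeq2 gave no adjusted p for the difference of uc021ynx.1 or uc010sta.1, and 3 of the 4 had a mean count under 100. Depth and the lone RocA library together limit what can be called, and the simulation did not separate them: over all models simulated for RocA in naive cells, 58.2% of 2-fold and 20.9% of 1.5-fold changes were recovered.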

Other observations

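Footprints shifted with abundance as well as with listed length. Under RocA, the most abundant of 5 groups of models had a median log2 fold change of 0.39 in naive and 0.31 in aglaiacized cells, and the least abundant group had medians of -0.41 and -0.32. In DMSO the corresponding medians, aglaiacized over naive, were 0.04 and -0.06. Abundance was averaged over all 6 libraries, RocA included, so part of this trend is built into the grouping. In aglaiacized cells 15 models rose and 757 fell by at least 4-fold, against 927 and 2751 in naive cells. This split depends on the scaling factor, and 5 of the 15 rises rest on 6 to 8 counts in aglaiacized RocA.

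It was asked, after the correlation of the 2 responses had been seen, whether the aglaiacized response is 1 constant share of the naive response in every model. A line with a slope of 0.60, the ratio of the SDs, was set through the 20211 well-covered models. Of these, 26.6% lay outside the 95% interval that their SE gives around it, against 5% by chance. The SE comes from the DMSO pairs, and the variation between RocA libraries is unmeasured, so this does not decide the question. The excess may come from such variation or from transcripts that keep more of the naive response than others.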
